A study of Solanum lycopersicum with 4 samples.

How the data were processed

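Small RNA libraries from TAP-treated total RNA of tomato leaf were compared, 2 made with HD adapters and 2 with standard Illumina adapters. Groups and replicate numbers came from the sample labels. The labels do not say whether the libraries came from separate plants or from 1 RNA sample, so p-values measure only the spread between these libraries, which may be technical.

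The authors deposited 1 list per library in which identical reads had been collapsed, each line holding a distinct sequence and its whole-number count, with no other normalization. Sequence and count share 1 text field. Lengths run from 17 to 33 nt in the HD lists and from 17 to 41 nt in the standard lists, so the reads appear to have been trimmed. Reads holding part of the 5′ sequencing adapter remained in the lists and made up 0.770% to 13.5% of the library totals defined below. Trimmomatic 0.32 and Bowtie 1.1.1 are named per the submitters' processing notes, which also name mouse and human genome builds for 1 of the 4 samples; the role of each is not given in the sources used here. The lists hold no genome positions, and no tomato genome was used here, so sequences were not mapped.

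Counts were read with Python 3.11.15 and pandas 2.3.3. Reads of 18 to 30 nt formed the library totals, and CPM are counts per 1000000 of these. Reads of other lengths were set aside and are described apart from the comparisons. A list of 68 miRNA and siRNA sequences (38 guide families and 14 star families), a list of 14 other RNAs (tRNA, rRNA and snRNA members) and a list of 13 animal miRNAs were fixed before the data were examined. So were the comparisons, most alternatives and the rule for named items. The limma model took the place of the planned one, and some tests of explanations were chosen after their results had been seen. A read of 19 to 24 nt was assigned to a family when it contained positions 3 to 18 of a listed sequence. A read was assigned to a tRNA, rRNA or snRNA end when it contained the first 16 nt of the listed end, and to 5S rRNA, 5.8S rRNA or U6 snRNA when it was part of the listed sequence. Reads containing 12 nt of the 5′ sequencing adapter were counted as adapter reads, and kept. Families with near-identical members share reads, so a family sum is not that of a single gene.

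A count model of the edgeR kind had been planned, but edgeR and DESeq2 were not used, since sequence and count share 1 text field. The counts read from that field were whole numbers, so the field did not itself prevent a count model. limma 3.58.1 in R 4.3.3 took its place, with voom precision weights and robust empirical Bayes moderation on log2 CPM. Sequences were kept when at least 2 libraries reached 0.376 CPM, which is 10 reads at the median depth, and when the total was at least 15 reads. Library sizes were scaled by trimmed mean of M-values (TMM) factors, which were 1.377 and 0.995 for the HD and 0.787 and 0.928 for the standard libraries. Tests were two-sided, HD minus standard, with the Benjamini-Hochberg threshold at 0.05. Families and classes were tested in a table with all other sequences. CPM in the text use library totals, whereas log2 fold changes use TMM-scaled sizes, so the ratio of CPM and the fold change of an item differ. The small standard error of an item with no reads in 1 group reflects the model, and its fold is given as a bound from 3 reads per library.

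The fit was tested on simulated data with the means and depths of these libraries and a dispersion of 0.1321, over 204378 sequences, and shares recovered are of the changed sequences that passed the filter. Where 60 percent of sequences changed, 77.1% of 4-fold, 99.9% of 16-fold and 100% of 64-fold changes were recovered, and 2.74% of unchanged sequences were called. Where 200 sequences of at least 10 CPM changed, 35.8% of 4-fold and 100% of 16-fold changes were recovered. Where 200 sequences of any abundance changed, 1.67% of 4-fold, 18.5% of 16-fold and 16.7% of 64-fold changes were recovered. The simulated changes were split near evenly between higher and lower, and both adapter kinds had the same dispersion. The simulation therefore does not give the error rate where changes are lopsided or the kinds differ in spread.

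Shares of lengths, of first nucleotides, of the 20 most abundant sequences, of canonical isomiRs and of guide strands are given per library with mean and SD and no test. Distinct sequences were counted after thinning each library to the smallest with a fixed seed. Replicates were compared before averaging. Over sequences of at least 10 CPM, the chi-square per degree of freedom was 97.0 between the HD libraries and 1306 between the standard libraries, far above the 1 of read-counting noise, so no library was taken for another deposited again. Separate preparations of 1 RNA sample would also exceed 1, so this does not show that the libraries came from separate samples.

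Named items followed a fixed rule. It takes called families with at least 10 CPM in either group, up to 10 in each direction by fold change, and the 5 most abundant families. Outside the lists it takes the 4 higher and 4 lower called sequences with the largest change, at least 10 CPM and no overlap between groups, and all listed classes. For isomiR and guide shares it takes the 3 families with the largest difference in each direction. Alternatives covered the scaling, the filter, a replicate block, each library left out in turn, a narrower length window, exact matching and reads held by single sequences.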

Results

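Small RNA from tomato (Solanum lycopersicum) leaf was sequenced from libraries built with 2 kinds of adapter. The RNA had been treated with tobacco acid pyrophosphatase (TAP), an enzyme that leaves a 5′ monophosphate on capped and triphosphate ends so that they can be ligated. HD (high definition) adapters carry random bases at the ends that are joined to the RNA, so that each RNA meets a pool of different adapter ends, whereas the standard Illumina adapters have a fixed sequence. There were 2 libraries per adapter kind. The HD libraries held 11524624 and 21173271 reads and the standard libraries 35879317 and 37587175. Reads of 18 to 30 nt numbered 11062693 and 20221101 in the HD libraries and 32968152 and 34823290 in the standard libraries, and fell on 3960977, 6855581, 7454470 and 5185462 distinct sequences in the same order. A count of 0 in these libraries allows up to 0.271, 0.148, 0.091 and 0.0861 counts per 1000000 reads (CPM), a limit that covers counting error only. Shares and CPM below are the mean ± SD of the 2 libraries of an adapter kind.

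The first question was how reads were spread over lengths. In the HD libraries 24-nt reads, the size of the small interfering RNAs that guide DNA methylation in plants, made up 57.2% ± 3.20 (SD, n = 2) of reads of 18 to 30 nt, against 11.3% ± 0.420 (SD, n = 2) in the standard libraries, a ratio of 5.05. The most common length in the standard libraries was 22 nt, with 22.1% ± 1.76 of reads against 9.78% ± 0.945 in the HD libraries. Reads of 21 nt, the size of most plant miRNAs, made up 7.78% ± 0.798 with HD and 9.96% ± 0.246 with standard adapters, and reads of 23 nt 11.4% ± 1.03 and 17.3% ± 1.82. At each of the 13 lengths the groups did not overlap, and 24 nt was the only one with the higher share in the HD libraries. The shares of a library have a fixed total, so the high share at 24 nt lowers those of all other lengths. A lower share at another length therefore does not by itself show that its RNAs were captured less well. One sequence at each of 2 lengths weighed on these shares. Without the most abundant 24-nt and 22-nt sequences and the reads holding their cores, the ratio of the 24-nt shares was 4.18 and that of the 22-nt shares 0.822, in place of 0.444. No test was run on shares, since 2 libraries against 2 cannot give a two-sided exact permutation p below 0.333.

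**Figure D1:**
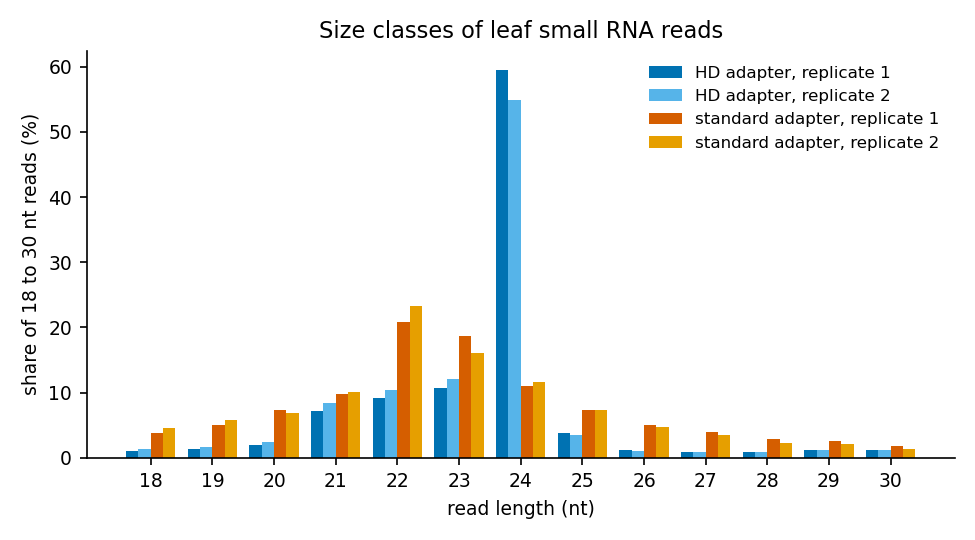
Share of 18 to 30 nt reads (y axis, percent) at each read length (x axis, nt), with 1 bar per library. At 24 nt the HD libraries stand at 59.5% and 54.97% and the standard libraries at 11.0% and 11.6%, while the standard libraries are higher at every other length shown.

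The first nucleotide of a plant small RNA goes with the Argonaute protein that takes it up, with A typical of 24-nt siRNAs and U, read as T, of 21-nt miRNAs. At 24 nt, 73.7% ± 2.78 of reads in the HD libraries began with A, against 49.4% ± 3.35 in the standard libraries, and G was the first nucleotide of 9.56% ± 0.987 and 20.4% ± 1.88. Without the most abundant 24-nt sequence the shares of A were 68.0% ± 0.730 and 48.8% ± 3.46. At 21 nt, T began 44.6% ± 0.177 of HD reads and 35.5% ± 5.97 of standard reads, a difference of 9.12 percentage points that was 3.38 for distinct sequences, 13.3 without standard replicate 1 and 4.898 without standard replicate 2. At 22 nt, T began 25.8% ± 1.29 of HD reads and 8.45% ± 0.653 of standard reads, while A began 54.2% ± 1.45 and 78.7% ± 0.627. The 22-nt shares carried the most abundant 22-nt sequence, and without it T began 38.7% ± 0.433 and 24.001% ± 6.61 and A 31.8% ± 0.597 and 40.2% ± 10.2 of 22-nt reads.

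Distinct sequences were then compared one by one. Of 204378 sequences tested with limma-voom at a Benjamini-Hochberg threshold of 0.05, 75382 were higher and 57819 lower in the HD libraries. The direction followed length. Among 97286 tested sequences of 24 nt, 59244 were higher and 4566 lower, with a median log2 fold change of 4.22. At 23 nt 4405 were higher and 14898 lower, and at 21 nt 3378 were higher and 4962 lower. At 22 nt the split was 4845 higher and 4520 lower. At all other lengths fewer sequences were higher than lower. Reads of 1 adapter kind are enough to pass the filter, so a length with more reads in 1 kind admits more sequences high in that kind. The split by length is thus no separate support for the shares of lengths. The median log2 fold change over all tested sequences was 1.75. It was -0.836 with no filter beyond 10 reads, -1.01 without HD replicate 1, -1.66 without HD replicate 2 and 0.437 with limma's trend in place of voom. When a library was left out, the scaling factors were also set anew and the filter admitted more sequences. The number of calls moved with all of these changes together. It was 54246 without HD replicate 2 and 206997 without standard replicate 1, and 80.2% of calls were higher in the HD libraries in the former case against 45.4% without HD replicate 1.

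**Figure D2:**
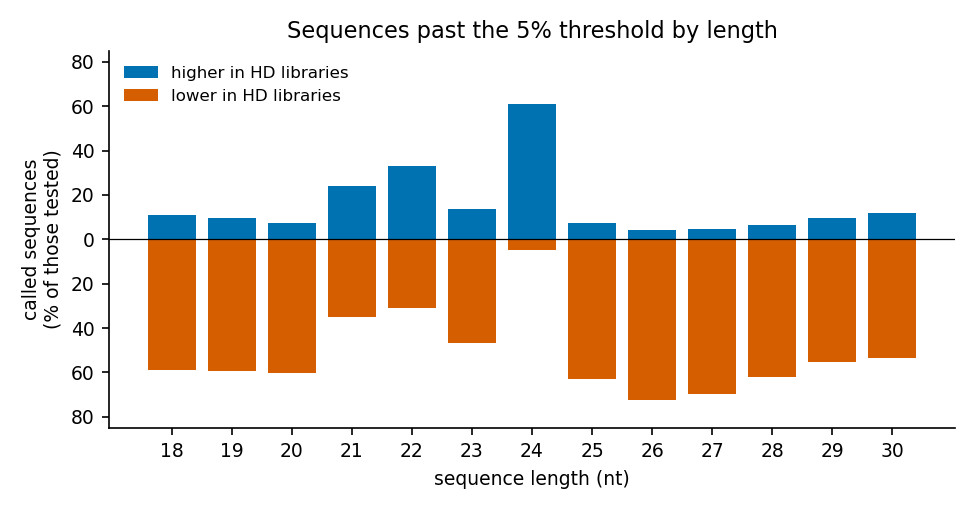
Share of the tested sequences of each length (x axis, nt) called higher in the HD libraries (bars above 0) or lower (bars below 0), in percent of the sequences tested at that length (y axis). At 24 nt 60.9% were higher and 4.69% lower, while at 26 nt 4.17% were higher and 72.4% lower.

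The largest differences among sequences outside the lists were near presence against absence. The 24-nt sequence AGCCAATGATGATTTTTATATAAA had 1489978 and 1445789 reads in the HD libraries, which was 13.5% and 7.15% of their reads, and 2 and 3 reads in the standard libraries (limma adjusted p = 0.00203). AAGCCAATGATGATTTTTATATAAA, the same sequence with 1 more nucleotide in front, had 3723 ± 1619 CPM with HD and no read with standard adapters, at least 42000-fold higher when 3 reads per standard library are taken as the limit. GCCAATGATGATTTTTATATAAA, with 1 nucleotide less in front, had 2382 ± 1010 CPM with HD and 2 reads in 1 standard library. The fourth, AGATGAGCTCAACGAGAACAGAAATCT, had 751 ± 345 CPM with HD and no standard read, at least 8480-fold higher. In the other direction, TAGAGTTCTACAGTCCGACGATC, which holds part of the 5′ sequencing adapter, had 1994 ± 2535 CPM in the standard libraries and no HD read. CTGCGCGCTCCGGACGCTGGCCT had 253 ± 77.3 CPM and AGGCTGTGATGATTAAGATTAAGGTGTT 253 ± 116 CPM with standard adapters, and GTCAATTTTGAACTCAAAGG had 130 ± 80.5 CPM, all 3 with no HD read, at least 1200-, 1200- and 621-fold lower with HD. These sequences were not matched to a genome, so their origin is not established here. The most abundant sequence of the standard libraries, AGTTACTAATTCATGATCTGGC of 22 nt, made up 14.1% ± 2.73 of their reads and 3.24% ± 0.574 of HD reads; it was chosen after its values were seen.

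Of the listed miRNA and siRNA families, both directions occurred. Among 43 strands tested (36 guides and 7 stars), 13 were higher in the HD libraries, 8 were lower and 22 were not called at the threshold over all sequences and sums tested. Adjusted over the list alone, 9 were higher, 7 lower and 27 not called. With library totals alone as the scaling, 21 were higher and 8 lower, and with median-of-ratios factors 20 were higher. The largest rise was that of miR5300, a regulator of NLR-type disease resistance genes in Solanaceae, with 87.7 ± 11.1 CPM in the HD and 2.96 ± 0.281 CPM in the standard libraries (log2 fold change 4.39 ± 0.511 SE, adjusted p = 0.00231). The related miR482 had 362 ± 13.6 and 30.96 ± 1.87 CPM (log2 fold change 3.06), and miR6022, a Solanaceae miRNA, 343 ± 52.3 and 34.1 ± 11.1 CPM (log2 fold change 2.87). Of the 12 guides listed as Solanaceae or NLR-targeting, 3 were higher, 1 was lower and 8 were not called; adjusted over the list alone 3 were higher and none lower.

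Of the other 24 guides 8 were higher, 5 were lower and 11 were not called, and adjusted over the list alone 5 were higher and 5 lower. miR159, which targets MYB transcription factors, had 3387 ± 393 CPM with HD and 251 ± 118 CPM with standard adapters (log2 fold change 3.34 ± 0.556 SE, adjusted p = 0.00613). miR171, which targets GRAS-domain regulators, had 589 ± 54.6 and 58.7 ± 9.72 CPM, and miR167, which targets auxin response factors, 2211 ± 356 and 364 ± 45.8 CPM. Also higher were miR156, which targets SPL factors, with a log2 fold change of 2.07, the TAS3 trans-acting siRNA with 2.06, miR172, which targets AP2-type factors, with 1.85, and the star strand of miR162 with 1.75. The remaining higher strands, outside the rule for named items and named after their values were seen, were miR319 (1.67), miR395 (2.696) and the star strand of miR156 (2.64), the last 2 under 10 CPM. Adjusted over the list alone, miR156, miR172, the miR162 star and miR319 were no longer past the threshold (adjusted p = 0.0541, 0.0541, 0.0603 and 0.0546). With reads of 20 to 24 nt only, miR156 (1.516) and the miR162 star (1.142) were not called. Counting only reads identical to a listed sequence, the miR162 star (1.469) was not called and miR172 rose to 5.795. Without standard replicate 2, miR172 had 0.9617 and the miR162 star 0.7149. miR156 had 3.19 without HD replicate 1 and 1.384 without standard replicate 1.

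miR166, which targets class III HD-ZIP factors, showed the largest fall. It had 795 ± 1.13 CPM in the HD and 8506 ± 2063 CPM in the standard libraries (log2 fold change -3.89 ± 0.468 SE, adjusted p = 0.00244). Its star strand had 1134 ± 88.9 and 3152 ± 652 CPM. miR408, linked to copper supply, fell with a log2 fold change of -3.53, miR169, which targets NF-YA factors, with -3.19, and the star strand of miR168 with -3.05. miR6023 (-2.01) and miR393, which targets auxin receptors (-1.75), were also lower. So was miR165 (-2.99), which had under 10 CPM and was named after its values were seen. It rested on 2 and 4 reads in the HD and 30 and 54 in the standard libraries. Leaving out either HD library also set the filter and the scaling factors anew. These fits ended the calls of miR6023, the miR166 star and miR393. They brought miR166 to a log2 fold change of -2.98 without HD replicate 1 and -3.07 without HD replicate 2. Counting only reads identical to a listed sequence turned miR393 to a log2 fold change of 3.65 and miR169 to 1.09. Of the 5 most abundant listed strands, miR162, which targets DCL1, had 4504 ± 422 and 3320 ± 619 CPM (log2 fold change -0.04, adjusted p = 0.946) and miR396, which targets growth-regulating factors, 2632 ± 1028 and 1328 ± 591 CPM (log2 fold change 0.51, adjusted p = 0.488). Without standard replicate 2 the log2 fold change was -0.923 for miR162 and 0.322 for miR396. Without HD replicate 1 that of miR396 was 1.83. The scaling factors without standard replicate 2 were 1.289 and 1.343 for the HD libraries and 0.578 for standard replicate 1. On CPM, which lack this scaling, miR162 was higher with HD. All listed miRNAs and siRNAs together made up 2.08% ± 0.235 of HD reads and 2.19% ± 0.218 of standard reads, and without miR166 1.89% ± 0.244 and 1.03% ± 0.0771.

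**Figure D3:**
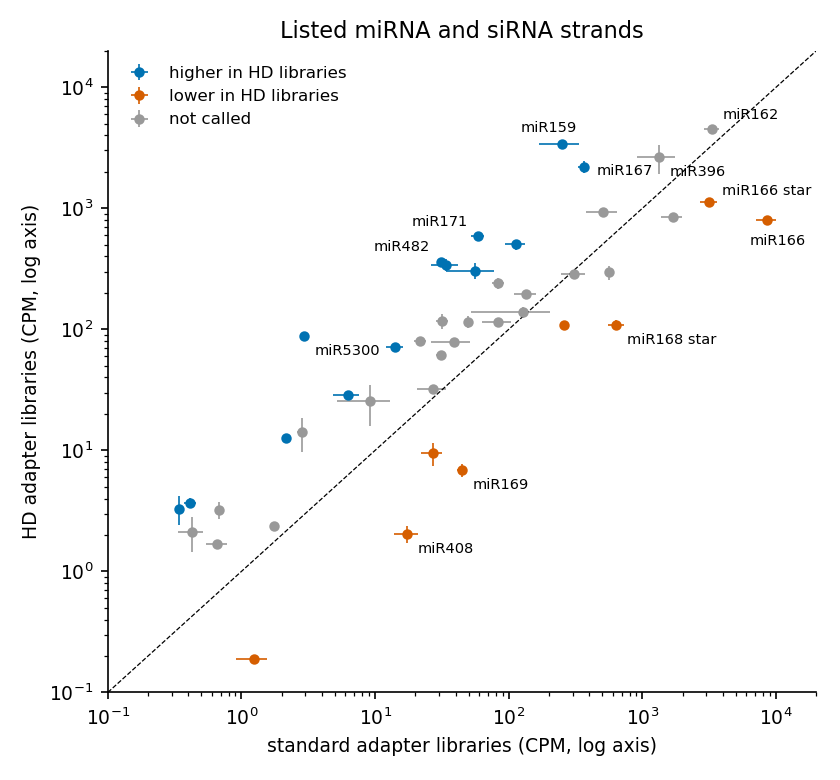
Mean CPM of each tested miRNA or siRNA strand in the HD libraries (y axis, log scale) against the standard libraries (x axis, log scale), with lines from the lower to the higher library and the dashed line marking equal CPM. Colours give the limma-voom call, with 13 strands higher in HD, 8 lower and 22 not called; miR159 lies at 3387 against 251 CPM and miR166 at 795 against 8506 CPM.

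The adapters also differed in which forms of a miRNA they returned. The canonical isomiR share is the share of a guide's or star's reads that are exactly a listed sequence, and 30 guides and stars had at least 100 reads in every library. Its median over these was 76.2% ± 0.724 in the HD and 37.3% ± 9.44 in the standard libraries. It was higher with HD, without overlap, in 23 of them and lower in 5, and it overlapped in 2, where chance keeps 33.3% from overlapping. The largest differences were those of miR160 (93.1% ± 1.13 against 2.31% ± 0.134), miR393 (77.8% ± 1.77 against 1.93% ± 0.697) and miR164 (86.8% ± 0.807 against 12.5% ± 1.36). In the standard libraries 36.7% ± 0.611 of miR164 reads were TGGAGAAGCAGGGCACGTGC, which lacks the last nucleotide of the listed form, and 59.97% ± 2.94 of miR393 reads were TCCAAAGGGATCGCATTGATTTT, a form with 0.627% ± 0.329 of the HD reads. miR4376 (6.47% ± 0.378 with HD against 24.9% ± 3.11), the star strand of miR162 (74.3% ± 1.94 against 91.3% ± 0.622) and miR319 (1.25% ± 0.143 against 3.31% ± 0.241) had the lower share with HD. For miR166 the most common form of the standard libraries was TCTCGGACCAGGCTTCATTCC, which begins 2 nucleotides before the listed one and held 58.8% ± 1.68 of reads against 29.4% ± 4.06 with HD.

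**Figure D4:**
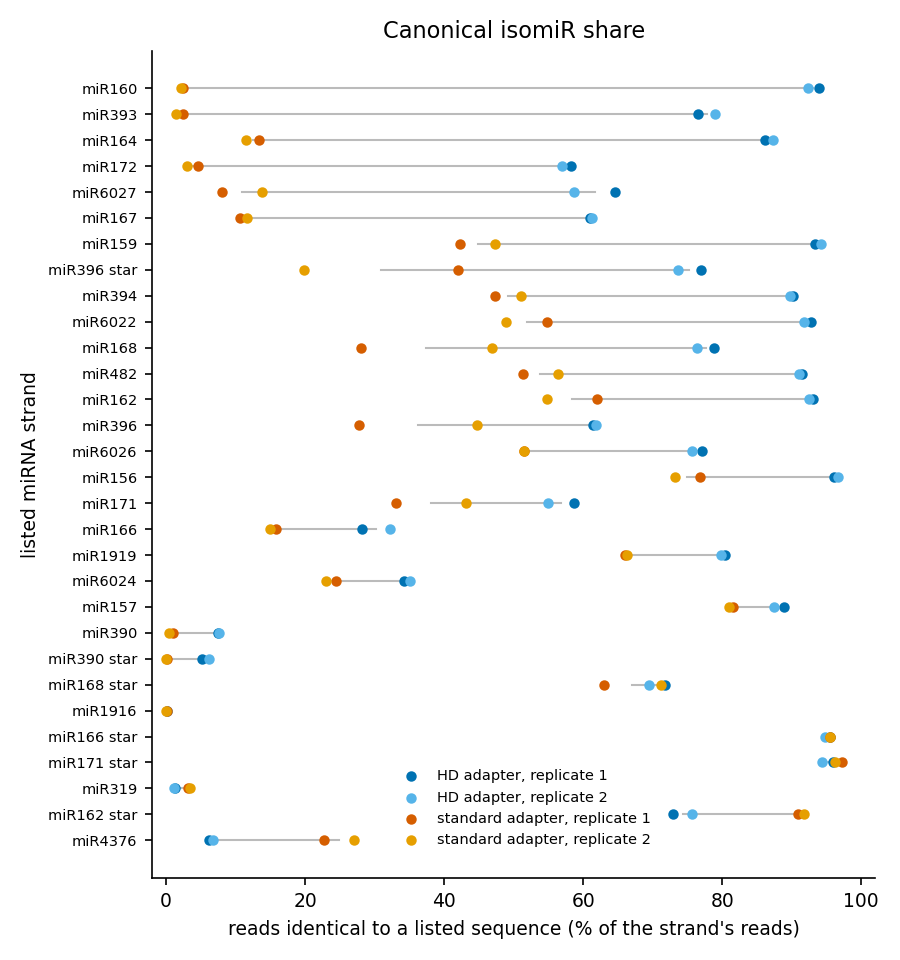
Share of reads identical to a listed sequence (x axis, percent of the strand's reads) for each of 30 listed miRNA strands (y axis), with 1 point per library and a grey line between the group means. Most strands lie further to the right in the HD libraries, as with miR160 at 93.1% against 2.31%. miR4376, whose main HD form is not a listed one, lies further to the left.

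Of families with both strands listed, 13 had enough reads in every library. Over these the share of guide reads in guide plus star reads had a median difference of 0 between adapters. Groups were apart for the families named here, where chance keeps 33.3% of families from overlapping. It was 67.2% ± 1.48 for miR171 with HD and 16.2% ± 1.72 with standard adapters, 89.6% ± 0.932 and 43.8% ± 4.66 for miR168, and 70.9% ± 3.63 and 58.1% ± 3.21 for miR390. It was lower with HD for miR166 (41.3% ± 1.87 against 72.4% ± 8.93) and for miR162 (99.4% ± 0.120 against 99.8% ± 0.0241). No other family had groups apart.

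TAP treatment opens capped and triphosphate ends, and fragments of structural RNAs were therefore counted as classes. Of 14 listed members, 1 was higher in the HD libraries, 8 were lower and 5 were not called, with the same split adjusted over the list alone. Fragments of 5.8S rRNA made up 0.223% ± 0.0231 of HD and 1.18% ± 0.150 of standard reads (log2 fold change -2.89), and 5S rRNA 0.0238% ± 0.00298 and 0.155% ± 0.0103 (-3.20). The 5′ ends of 18S and 25S rRNA fell with log2 fold changes of -2.28 and -2.25, and those of U1 and U2 snRNA, which carry a cap, with -3.27 and -1.97. Without HD replicate 1 the U2, 18S and 25S calls were lost, and without HD replicate 2 the U2 and 25S calls. U6 snRNA was not called (-0.33, adjusted p = 0.571), except as lower without standard replicate 2. Of the 7 tRNA 5′ ends, tRNA-Gly was higher (2436 ± 237 against 91.9 ± 3.41 CPM, log2 fold change 4.24), tRNA-Ala was lower (162 ± 22.3 against 1549 ± 157 CPM, -3.75) and tRNA-Glu was lower (0.3002 ± 0.215 against 31.1 ± 18.2 CPM, -7.03). The ends of chloroplast tRNA-His (1.63), tRNA-Asp (0.68), tRNA-Arg (-1.22) and initiator tRNA-Met (-0.88) were not called. Each tRNA was listed by 1 end sequence, so tRNAs for the same amino acid with another 5′ end are not covered. With reads of 20 to 24 nt only, tRNA-Asp (-2.04) and tRNA-Arg (-2.66) were called lower and tRNA-His turned to -1.36. Without either HD library and with no filter beyond 10 reads tRNA-His was called higher, and without either standard library tRNA-Arg and tRNA-Met were called lower. tRNA-Asp was called higher without HD replicate 1 and without standard replicate 1, and lower without standard replicate 2. Together the tRNA ends made up 0.453% ± 0.0536 of HD and 0.227% ± 0.00185 of standard reads.

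The variety of sequences was compared at equal depth. With each library thinned to 11062693 reads, the HD libraries held 4124100 ± 230630 distinct sequences and the standard libraries 3085100 ± 358180, a ratio of 1.34, and the groups did not overlap. Among 24-nt reads alone, thinned to 3635922 reads, the numbers were 1445400 ± 110650 and 867590 ± 254510. The 20 most abundant sequences took 17.7% ± 3.96 of HD and 25.4% ± 2.99 of standard reads, and 4.28% ± 0.168 and 8.13% ± 0.745 once the most abundant 24-nt and 22-nt sequences and adapter reads were left out. The difference of -7.69 percentage points was -4.89 without HD replicate 2. Across sequences past the filter, Spearman's rho of log2(CPM + 1) was 0.907 between the HD libraries and 0.905 between the standard libraries. The filter admits sequences found with 1 adapter kind only. This can raise the values within a kind, so they do not measure agreement among shared sequences, and the correlation between kinds is not given. Across the listed miRNAs and siRNAs, Spearman's rho was 0.990 and 0.981 within adapters and 0.877 to 0.900 between them. Sequences are not independent replicates, so these carry no p.

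Listed animal miRNAs without a plant counterpart served as a measure of reads from other libraries. They had 12 and 24 reads in the HD libraries and 44 and 50 in the standard libraries, which is 1.08, 1.19, 1.33 and 1.44 CPM.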

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

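The tests of abundant sequences and adapter reads, of size selection, of carry-over from an animal library, of standard reads among sequences sharing 1 end and of trimming were chosen after their results had been seen, and the other tests before. The comparison is between adapters, so no biological explanation was tested, and whether both adapter kinds were given the same RNA is not stated.

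Adapter reads were kept in the main comparisons, reads of other lengths were left out of them, and animal miRNAs were not among the listed families. All stood above the level that a count of 0 allows. Reads holding the 5′ sequencing adapter made up 13.5% of 18 to 30 nt reads in standard replicate 1, against 0.770% in standard replicate 2 and 1.63% and 1.29% in the HD libraries. Reads of 31 to 33 nt made up 3.49% ± 0.229 (SD) of all reads in the HD libraries and 3.596% ± 0.649 in the standard libraries. Reads of 17 nt made up 0.764% ± 0.117 and 3.42% ± 0.430, and reads of 34 to 41 nt 0.717% ± 0.319 in the standard libraries, with none in the HD lists, which end at 33 nt. Listed animal miRNAs had 130 reads over the 4 libraries, of which miR-124 took 11, 21, 19 and 15 and miR-10b 16 and 19 in the standard libraries and none in the HD libraries.

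The share of 24-nt reads was 5.05 times as high with HD adapters. A few abundant sequences and adapter reads do not account for it, since without them the ratio was 3.995. Loss of 1 or 2 nucleotides at the 3′ end in the standard libraries could account for part of it. In both adapter kinds, 22- and 23-nt reads that start a 24-nt sequence were counted as 24 nt. The ratio was then 1.73 (68.9% ± 1.90 against 39.9% ± 0.290), and 2.33 without the abundant sequences. Starts of rare 24-nt sequences were not counted, and the HD share was raised too. Before this counting the HD share was 57.2% ± 3.20. All 22- to 24-nt reads of the standard libraries together made up 50.7% ± 0.365. Even this upper limit fell short of the HD share, by a narrow margin. A preference for single end nucleotides is argued against as the whole cause by the odds of 24-nt against 21-nt reads. They were higher with HD by a median of 4.65 within 16 classes of first and last nucleotide. The classes ran from 1.43 for T and G to 11.8 for A and T. The rule set beforehand asked for over 1.5 in every class, which 15 reached, so by that rule the test could not decide. The reading by the median departs from it. A size selection that acts on neighbouring lengths together is argued against, since 24-nt reads over 23-nt reads were 7.70 times and over 25-nt reads 10.004 times as high with HD. Preferences for longer end sequences stay open.

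The 24-nt sequence AGCCAATGATGATTTTTATATAAA was the most abundant in the HD libraries and close to absent from the standard libraries. Carry-over from an animal library is argued against by the listed animal miRNAs, whose reads came to 0.00123% of those of this sequence. A preference for its first 4 or its last 4 nucleotides alone is argued against, since 62.1% of 219 other 24-nt sequences sharing the first and 48.9% of 814 sharing the last had reads in the standard libraries. Their median log2 fold change of 4.97 decides nothing, because with no standard read at all their HD reads would give 10.53 at most (the highest was 10.099), against 19.67 for the sequence in the same fit. A preference for both ends together stays open, since all 47 tested sequences with both ends differ from it by 1 or 2 nucleotides. Its reads in HD replicate 1 were 1.03 times those in replicate 2, whereas total reads were 0.547 times. A source other than leaf RNA stays open, as no genome was searched, and so does RNA that differed between the adapter kinds.

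The canonical isomiR share was higher with HD adapters. Trimming that took the last nucleotide from all reads of the standard libraries is argued against by 2 of 10 abundant miRNA strands, the star strands of miR166 and miR171, whose canonical shares differed by under 2 percentage points. A preference at the 3′ ligation of the standard adapters is a candidate explanation. The share of reads with the listed 3′ end was higher with HD by a median of 24.7 percentage points over 30 miRNA strands. It was higher without overlap in 27 and lower in 2. The end was matched over 8 nt, so an unlisted form that differs within them is counted as another end. The share with the listed 5′ end differed by a median of -0.241 percentage points, being higher with HD in 14 and lower in 14 without overlap, so it showed no common fall, and a preference at the 5′ ligation stays open for single strands. Trimming that depends on the read's sequence would also act on the 3′ end and stays open.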

How the results depend on the processing

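Limits of these results are the 2 libraries per group and a number of calls that moved when single libraries were left out. The filter and the scaling factors were set anew in those fits. A call lost or gained there need not be owed to the reads of the library left out. The planned DESeq2 test was not run, although the counts read from the text field were whole numbers. Median-of-ratios factors and the block were fitted in limma. Alternatives without adapter reads, without the most abundant sequences, and with limma's trend were chosen after seeing the data. No call of the sequence test reversed under the alternatives run, but without HD replicate 2 only 44510 of the 93448 calls still tested were kept, and without HD replicate 1 92621 of 113736. Of the alternative values for 33 named families and classes, 330 kept direction and side of the threshold, 15 lost the call, 16 gained one in the same direction and 20 changed sign, of which 2 had been called, 2 were not called before and called with the other sign after, and 16 were called in neither fit. The cause of the changes below was not tested unless the alternative's construction shows it.

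With no filter beyond 10 reads, 202015 sequences were called, 73.0% of them higher, from 673041 tested. Leaving out each replicate in turn gave 54246 to 206997 called sequences, 45.4% to 80.2% of them higher, 23 to 35 called families, 19 to 23 of them higher, and 1 to 3 higher classes; the lone library is then assumed to vary like the others. Median-of-ratios factors gave 20 higher families and library totals 21. With a replicate block, 169872 sequences, 29 families and 11 classes were called, with 2 higher classes, as many as without the filter, tRNA-His being called higher in both (1.624 and 1.973) and tRNA-Arg lower (-1.21) with the block; the replicate numbers share no stated origin, and the correlation of the deviations of same-numbered libraries was 0.0679, and 0.142 for sequences of at least 10 CPM. With reads identical to a listed sequence only, 22 families were called, 18 of them higher, with 15 calls shared with the main fit; miR169 went to a log2 fold change of 1.09, miR393 to 3.65, called higher, and miR162 to 0.6433. The difference between the adapters' median guide shares went from -0.414 over 13 families to 0.0398 percentage points over 9, while the median of the differences per family was 0 in both. Of items not called, miR162 went from -0.04 to 0.1156 with median-of-ratios factors, 0.4574 with library totals, 0.3087 without the filter and 0.01738 without adapter reads, and U6 snRNA from -0.33 to 0.1519 with library totals and 0.01529 without the filter. With reads of 20 to 24 nt only, miR396 went to -0.02196, tRNA-His to -1.358 and tRNA-Asp to -2.035, the last called. Leaving out each replicate in turn gave -0.9227 to 0.9684 for miR162, -0.02874 to 1.826 for miR396, -1.243 to 0.5761 for U6 snRNA, -1.622 to 0.2556 for initiator tRNA-Met and -0.3813 to 1.621 for tRNA-Asp.

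The ratio of 24-nt shares was 5.42 for sequences of at least 2 reads, 3.79 for distinct sequences, 4.18 without the most abundant sequences and 3.995 without these and adapter reads. The ratio for distinct sequences was 0.697 at 21 nt and 0.857 at 22 nt, and that of 22-nt reads was 0.822 and 0.878 under the same omissions. The difference in 24-nt reads starting with A was 15.5 percentage points for distinct sequences and 19.2 without the most abundant sequences. Distinct 24-nt sequences at equal depth had a ratio of 1.67.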

Other observations

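The tests named here were set before their results were seen, and the values on longer reads were looked at without a fixed rule. Reads of 31 to 33 nt, the size of tRNA fragments cut at the anticodon, differed between adapters by sequence although their total share did not. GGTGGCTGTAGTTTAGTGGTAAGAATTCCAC of 31 nt was the most abundant of these in both HD libraries, with 5745 ± 728 counts per 1000000 of all reads against 145 ± 24.4 in the standard libraries. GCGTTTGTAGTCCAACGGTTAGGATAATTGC of 31 nt was the most abundant in both standard libraries, with 2323 ± 652 against 1019 ± 64.4 in the HD libraries. Reads of 31 to 33 nt from the tRNA-Gly 5′ end had 3589 ± 443 with HD and 9.39 ± 0.230 with standard adapters.

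A hypothesis was that the ends of 24-nt sequences set part of their difference between adapters. Over 96786 sequences, the 3 nucleotides at each end predicted, in sequences held out of the fit, a share of 0.132 of the variance in log2 fold change, against 0.00931 for 6 interior positions. The first 3 positions gave 0.0820 and the last 3 gave 0.0506. Sequences starting with A had a median log2 fold change of 4.49 and those starting with C 2.87, and those ending with A had 4.68 and with C 3.77. The ends thus predicted the fold change better than the interior did, and most of the variance was left without a predictor. A preference at both ligations could give this, but the test cannot tell it from other causes. Where a sequence had no standard read, its fold change was set by its HD reads. Ends that go with the kind of small RNA, as a first A does with 24-nt siRNAs, could then predict it without any ligation preference. Sequences are not independent replicates, so no p is given.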
